A study of Mus musculus with 8 samples.

How the data were processed

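RNA was measured in 8 libraries of embryonic mouse cerebral cortex, 4 Taf8 wild-type and 4 Taf8-deleted. Per the labels' protocols, RNA was isolated with an RNeasy kit and made into libraries with a stranded poly(A) kit. Per the series' design text, each library came from its own embryo and was read in pairs on a NextSeq instrument. The deposited values are raw read counts per Entrez gene, whole numbers with no normalization, and per the submitters' processing notes they were made with Subread 1.5.0 and featureCounts on the mouse genome mm10. The deposited table also gives the gene length that the counting tool used. The gene annotation, the treatment of reads that map to several places and the strand setting of the counting are not given in the sources used here. Overlapping and antisense genes and genes with near-identical copies are therefore uncertain. Gapdh, which has many pseudogene copies, had 3.36 CPM in wild-type cortex.

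The count matrix held 27179 genes, and its values differed from the single-sample files in 0 places. Symbols came from a RefSeq gene table for 25275 genes and from GENCODE for 17, and 1887 genes had no symbol and kept their Entrez number. Coordinates are those of the RefSeq table of GRCm38.p6, the same sequence as mm10. Totals ran from 26312505 to 65523487 counts per library, so 3 counts correspond to 0.0458 to 0.114 CPM, a floor that covers counting error only. Within-group pairs of libraries differed by more than sampling noise, with a chi-square of 3.71 to 28.78 per degree of freedom, so no library was counted as a repeat of another.

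Groups were taken from the labels. Counts were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr filter, quasi-likelihood F-test, group as the term), with Benjamini-Hochberg adjustment over 15649 genes and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of its F statistic. CPM values use TMM-scaled library sizes. The 31 gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, for lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. List levels per library are mean log2 CPM of the tested members with a prior count of 2.

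Genes are named by a rule set before the data were examined. It takes Taf8, then the 12 higher and 12 lower genes with the largest log2 fold change among those past the threshold with groups that do not overlap and a mean of at least 5 CPM in the higher group. Xist, Tsix, Y-linked genes and unnamed or predicted genes were left out of that part. It also takes up to 4 members of each list by smallest adjusted p, and every tested TFIID subunit. Some genes that the rule takes are not reported here.

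The steps were tested on simulated counts for the comparison of Taf8-deleted with wild-type cortex, over 15649 genes with 200 changed. Of the changed genes, 77.6% were recovered at 1.5-fold and 89.6% at 2-fold, and 8 unchanged genes were called, 4.7% of all calls. A simulated set of 30 genes changed 1.3-fold was called with a preset and with an estimated correlation (camera adjusted p = 2.57e-39 and 0.000112), and 0 of 20 unchanged sets were called. The simulated genes varied independently of each other and few were changed. In the real data 59.2% of genes were called and estimated correlations within lists reached 0.679. The simulated error rates therefore do not carry over to the real genes and lists.

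Alternatives were other scalings (size factors, upper quartile, library size alone), no filter or 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom with and without quality weights, a replicate block, Xist as a covariate, each library left out in turn, the single-sample counts, a test against a 1.2-fold change, and a threshold of 0.01. Covariates for the meningeal and choroid plexus lists, and a fit without wild-type replicate 4 and deleted replicate 1, were added after seeing the data. DESeq2 was not used for the lists.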

Results

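Polyadenylated RNA of the embryonic mouse cerebral cortex was sequenced from 4 Taf8 wild-type and 4 Taf8-deleted embryos, each library from a separate embryo. Taf8 encodes a subunit of TFIID, the complex that binds core promoters and helps to recruit RNA polymerase II. The labels give the deleted embryos a null and a lox allele of Taf8. The embryonic day and the Cre driver are not given in the sources used here. The wild-type libraries held 30601897, 40838890, 65523487 and 38139435 counts in genes, and the Taf8-deleted libraries held 37465154, 30061556, 26312505 and 52777170. Every value below has n = 4 embryos per group, and levels are means ± SD in CPM, counts scaled to the size of the library. All 8 libraries expressed the Y-linked gene Ddx3y at 40.81 to 52.53 CPM and Xist at under 1 CPM. No animal number in the labels has its first part in both groups, so any litter or batch that it marks cannot be told apart from the Taf8 genotype. Wild-type replicates 1 to 3 share a first part (408.4, 408.5 and 408.6), while each deleted embryo has its own. If that part marks a litter, these 3 embryos are littermates. The wild-type SD may then understate the spread between litters, and the p-values may be too small.

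The first comparison asked whether Taf8 RNA was lost in the libraries labelled Taf8-deleted. Taf8 (Entrez gene 63856, chromosome 17, 47483364 to 47502321, minus strand, mm10) fell from 34.8 ± 2.75 CPM in wild-type cortex to 0.64 ± 0.15 CPM in Taf8-deleted cortex. The deleted level was 1.85% of wild-type, a log2 fold change of -5.75 (SE 0.12). All 4 deleted libraries, with 13 to 30 counts, lay below all 4 wild-type libraries, with 1160 to 2047 counts. The adjusted p was 1.45e-09 by edgeR's quasi-likelihood test. An exact two-sided permutation test of the log2 CPM gave p = 0.0286 over 70 permutations, the smallest p that 4 against 4 libraries allow. The counts are per gene, so they do not show which exons the remaining reads came from.

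**Figure D1:**
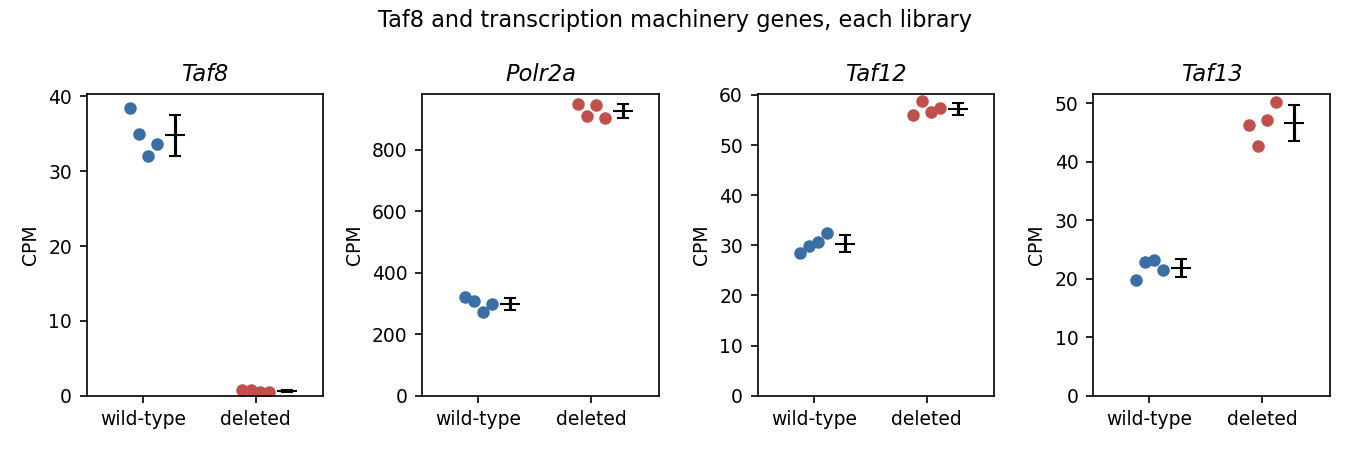
Level of Taf8, Polr2a, Taf12 and Taf13 in each library, in CPM, with 1 point per embryo and bars for the mean ± SD of 4 embryos. Taf8 averaged 0.64 CPM in Taf8-deleted cortex against 34.8 CPM in wild-type cortex, and the other 3 genes were higher in every deleted library than in every wild-type library.

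The second comparison asked which genes differed between Taf8-deleted and wild-type cortex. Of 15649 genes tested, 4624 were higher and 4633 were lower in Taf8-deleted cortex at a Benjamini-Hochberg adjusted p under 0.05, which is 59.2% of the genes. The scaling puts the middle of all genes near 0 (median log2 fold change 0.01), so higher and lower are relative to the other genes. A change in the amount of RNA shared by most genes would not show in these counts. Most differences were small, with a median absolute log2 fold change of 0.42 among the called genes. A change of at least 2-fold was seen in 857 of the higher and 484 of the lower genes. The groups did not overlap in 8385 genes, 53.6% of those tested, against 2.86% expected by chance. The first principal component held 68.1% of the variance and separated the groups. Correlations between libraries were 0.989 to 0.995 within a group and 0.968 to 0.977 between groups. When the change had to exceed 1.2-fold, 2307 genes were higher and 2328 lower.

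Histone genes, the homeobox gene Dbx1 and the chemokine gene Ccl27a were among the 12 genes with the largest rise. Dbx1, a transcription factor of neural progenitors (chromosome 7, 49631499 to 49636835), rose from 1.17 ± 0.196 to 16.7 ± 2.15 CPM, a log2 fold change of 3.85 (SE 0.14, adjusted p = 2.81e-08). Ccl27a (chromosome 4, 41769467 to 41774225) was 31.2-fold higher, at 13.3 ± 4.6 against 0.433 ± 0.176 CPM. The adaptor gene Dok2 was 12.7-fold higher, the transcription factor gene Mafa 7.99-fold and Lrrc51 7.98-fold. Ndufs5, a subunit gene of respiratory complex I, was 13.5-fold higher, at 8.72 ± 3.05 against 0.654 ± 0.143 CPM. The levels of Ccl27a, Ndufs5 and the histone genes are uncertain, because these genes have near-identical copies that can share reads. The other 6 of the 12 were the histone genes H4c8, H4c9, H2bc6, H2ac6, H2bc4 and H1f2.

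The 12 genes with the largest fall had levels 4.57-fold to 9.01-fold lower in Taf8-deleted cortex. The serotonin receptor gene Htr3a (chromosome 9, 48899213 to 48911152) was 9.01-fold lower, at 0.589 ± 0.236 against 5.25 ± 0.48 CPM (adjusted p = 7.42e-07). Aldh1a3, which makes retinoic acid (chromosome 7, 66390892 to 66427477), was 8.43-fold lower, and the fatty acid desaturase gene Scd1 was 7.26-fold lower, at 3.44 ± 0.138 against 25.2 ± 3.32 CPM. The receptor genes Gipr, Sstr3, Mc4r and Drd1 were 7.12-fold, 6.47-fold, 6.07-fold and 4.97-fold lower. The transcriptional repressor gene Bcl6 was 6.04-fold lower and the transcription factor gene Nfe2l3 was 4.88-fold lower. Dct, an enzyme of melanin synthesis, was 5.79-fold lower, the microRNA gene Mir9-2 was 4.97-fold lower, and the folate enzyme gene Aldh1l1 was 4.57-fold lower. Polyadenylated RNA was sequenced, so the Mir9-2 reads do not measure the mature microRNA.

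The other subunits of TFIID were mostly higher in Taf8-deleted cortex. Of 15 tested, 12 rose, 1 fell and 2 did not pass the test. Taf13 rose 2.13-fold, from 21.8 ± 1.55 to 46.6 ± 3.07 CPM (adjusted p = 3.96e-07). Taf12 rose 1.88-fold, from 30.4 ± 1.66 to 57.2 ± 1.19 CPM, and Taf5 rose 1.71-fold, from 29.7 ± 1.28 to 50.7 ± 1.37 CPM. Log2 fold changes were 1.19 for Taf4b, 0.68 for Taf9b, 0.54 for Taf6, 0.47 for Taf10, 0.40 for Taf2, 0.35 for Taf4, 0.33 for Taf11, 0.19 for Tbp and 0.16 for Taf9. Taf7 fell by 0.34 on the log2 scale, and the values that did not pass were 0.10 for Taf1 and -0.02 for Taf3. Taf1 passed with upper-quartile scaling (0.12), with library size alone (0.14), with voom quality weights (0.10) and without wild-type replicate 3 (0.12). The sign of Taf3 turned positive with the first 2 of these. With Xist as a covariate Taf2, Taf4, Taf6, Taf7, Taf9, Taf9b, Taf10, Taf11 and Tbp lost their calls (adjusted p = 0.0739 to 0.666). Xist, though low throughout, was higher in every deleted library than in every wild-type library. That fit can therefore hardly tell group from covariate. The list as a whole was higher by camera (median log2 fold change 0.40, adjusted p = 0.000279), a call lost with an estimated correlation between genes (adjusted p = 0.148).

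RNA polymerase II and general transcription factor genes also tended to be higher, with 16 of 30 higher, 3 lower and 11 not past the test. Polr2a, the largest subunit of the polymerase, rose 3.09-fold from 300.0 ± 19.5 to 927 ± 22.5 CPM (adjusted p = 9.93e-09). Gtf2a1, a subunit of TFIIA, rose 2.77-fold, Gtf2b 1.49-fold and the TFIIH helicase gene Ercc3 1.42-fold. The list had a median log2 fold change of 0.18 (camera adjusted p = 0.00365, and adjusted p = 0.252 with an estimated correlation). In the list of SAGA and ATAC coactivator subunits, which holds no gene of the TFIID list, 4 of 24 genes were higher, 10 were lower and 10 did not pass. Any subunit shared with TFIID is therefore not counted here. The lower ones included Tada1, with a log2 fold change of -0.70, and Supt7l, a subunit of the SAGA core, with -0.48. The SAGA and ATAC list was not called by camera (median -0.06, adjusted p = 0.257) and was called as lower by fry (adjusted p = 0.000313).

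**Figure D2:**
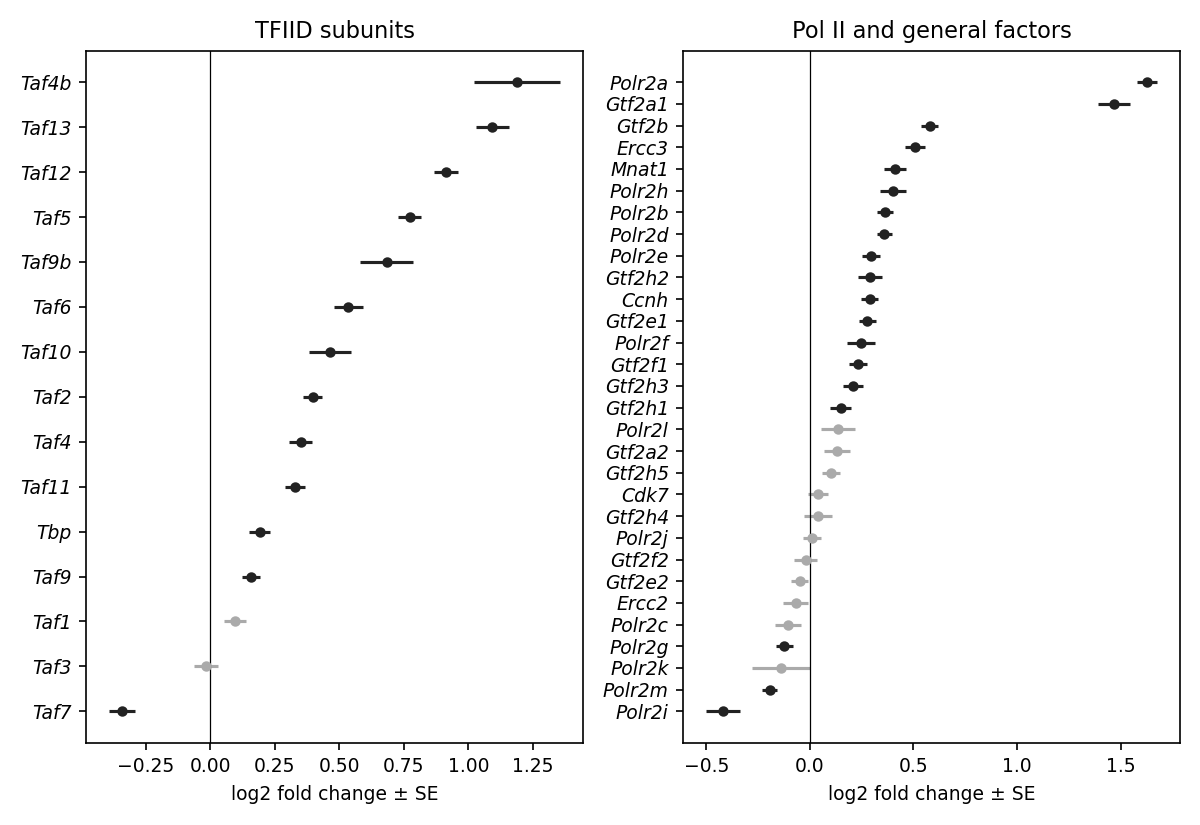
Log2 fold change (Taf8-deleted over wild-type) ± SE of each tested subunit gene of TFIID other than Taf8 (left) and of RNA polymerase II and the general transcription factors (right), with black points for adjusted p under 0.05 and grey points for the rest. Of 15 TFIID genes 12 were higher and 1 lower, and of 30 genes on the right 16 were higher and 3 lower.

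Genes of replication-dependent histones, which package newly made DNA, showed the largest shift of any list tested. Of 47 tested, 37 were higher, 1 was lower and 9 did not pass, with a median log2 fold change of 1.51. H1f2 rose from 12.7 ± 1.71 to 91.6 ± 1.65 CPM, and H2bc4 rose from 4.43 ± 0.743 to 44.1 ± 1.08 CPM. H4c9 (chromosome 13, 22040960 to 22041362) rose 15.6-fold, from 2.09 ± 0.0866 to 32.6 ± 2.58 CPM (adjusted p = 1.45e-09). Summed over all 63 histone genes in the table, the level rose 4.64-fold, from 65.3 ± 8.04 to 303 ± 11.2 CPM. Most such transcripts lack a poly(A) tail, so the libraries sample them only in part. The list was called by camera (adjusted p = 4.96e-10) and was not called with an estimated correlation (adjusted p = 0.252).

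**Figure D3:**
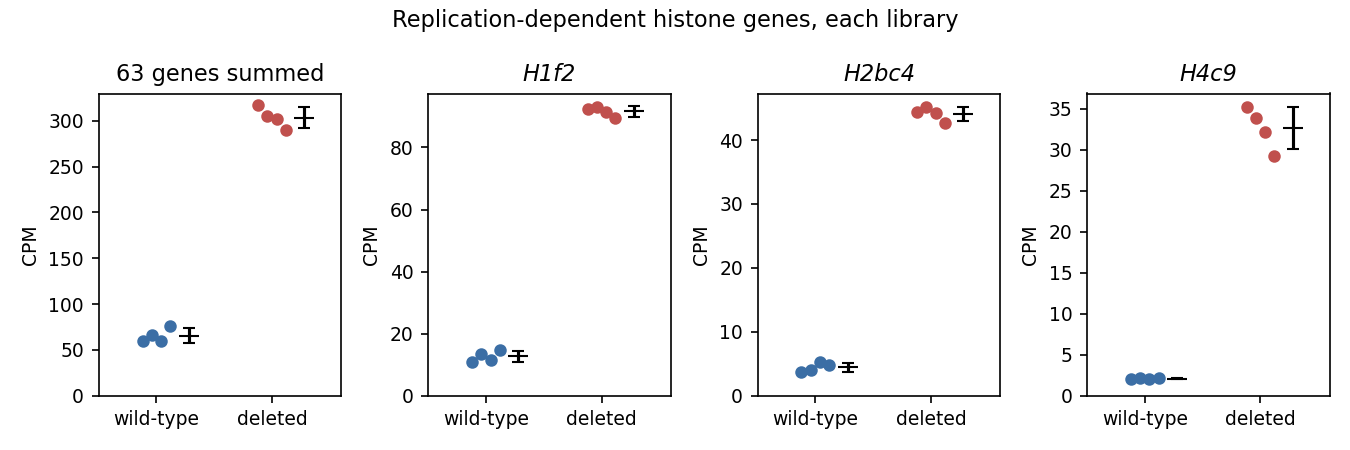
Level of replication-dependent histone genes in each library, in CPM, as the sum of 63 genes and for H1f2, H2bc4 and H4c9, with 1 point per embryo and bars for the mean ± SD of 4 embryos. The sum averaged 65.3 CPM in wild-type and 303 CPM in Taf8-deleted cortex.

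Markers of cortical neurons were lower in Taf8-deleted cortex. Among pan-neuronal markers 20 of 25 were lower, 1 was higher and 4 did not pass, among deep-layer markers 16 of 19 were lower and 1 was higher, and among upper-layer and callosal markers 15 of 19 were lower and 1 was higher. The synaptic vesicle gene Syn1 fell from 95.3 ± 3.8 to 61.0 ± 1.44 CPM, and the neuronal transcription factor gene Neurod2 fell from 394 ± 16.2 to 221 ± 14.6 CPM. The higher pan-neuronal marker was the neurofilament gene Nefm, at 1.58-fold. The higher genes of the other lists, picked out after their values were seen, were Nxph4 (deep-layer, log2 fold change 0.66) and Nectin3 (upper-layer, 0.45). Of the deep-layer genes Sox5 fell by 1.12, Bcl11b by 0.74 and Fezf2 by 0.73 on the log2 scale. Of the upper-layer and callosal genes Cux1 fell from 192 ± 14.3 to 116 ± 1.6 CPM, and the ephrin receptor gene Epha3 fell from 170.0 ± 6.63 to 96.7 ± 6.7 CPM. Median log2 fold changes were -0.41, -0.56 and -0.62, with camera adjusted p of 9.9e-05, 0.000314 and 0.000301. With an estimated correlation the adjusted p were 0.511, 0.413 and 0.252. Vascular and meningeal markers were higher in the same comparison, with median log2 fold changes of 0.33 and 1.23. With the meningeal level as a covariate the deep-layer median was -0.34, and the list was still called.

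Interneuron and ganglionic eminence markers were lower in 20 of 29 genes, higher in 4 and not past the test in 5. Gad2, an enzyme of GABA synthesis, fell from 148 ± 4.89 to 64.6 ± 4.26 CPM, and the interneuron transcription factor gene Lhx6 fell from 118 ± 6.13 to 56.4 ± 4.1 CPM. The list had a median of -0.23 (camera adjusted p = 0.00573, and adjusted p = 0.413 with an estimated correlation). Oligodendrocyte precursor and astrocyte markers were lower in 8 of 11 genes and higher in 0, including Aldh1l1, Sox10 and Egfr, with a median of -0.50 (camera adjusted p = 0.00362, and adjusted p = 0.252 with an estimated correlation). Cajal-Retzius markers went both ways, with 5 of 13 higher and 3 lower. The higher ones included Ebf3, at 58.4 ± 2.74 against 26.8 ± 1.99 CPM. The Cajal-Retzius median was -0.02 while the mean was 0.19 and the test pointed up (camera adjusted p = 0.559).

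Progenitor markers changed in both directions. Of 25 radial glia markers 13 were higher, 8 lower and 4 not past the test (median 0.17, camera adjusted p = 0.30). The intermediate filament gene Nes rose from 515 ± 42.2 to 979 ± 34.9 CPM, while Veph1 fell by 1.51 and the matrix gene Tnc by 0.85 on the log2 scale. Of 17 intermediate progenitor markers 7 were higher and 9 lower (median -0.24, camera adjusted p = 0.743). Btbd17 was 3.23-fold higher, the Notch ligand gene Dll1 1.99-fold and Hes6 1.95-fold, while Mfap4 fell from 60.6 ± 3.81 to 16.9 ± 1.31 CPM. Of 30 S-phase genes 14 were lower and 3 higher, including lower Gins1 at 13.1 ± 0.794 against 27.1 ± 2.08 CPM, and the list missed the threshold (median -0.17, camera adjusted p = 0.0708). It passed without wild-type replicate 3 (median -0.24) and without deleted replicate 2 (-0.20). Of 30 genes of G2 and mitosis 9 were lower, Ube2c among them with a log2 fold change of -0.86, and 4 were higher (median 0.00, camera adjusted p = 0.743).

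Targets of p53 and genes of the apoptosis machinery changed in both directions, and neither list was called by camera. Of 44 p53 targets 12 were higher, 10 lower and 22 not past the test (median 0.03, camera adjusted p = 0.744). Plk3 rose 2.4-fold and Ddb2 1.7-fold, and Sesn1 fell by 0.40 on the log2 scale. Of 31 apoptosis genes outside that list 9 were higher and 10 lower (median 0.05, camera adjusted p = 0.744). Leaving out 1 library moved the apoptosis median from -0.034 (without deleted replicate 3) to 0.094 (without wild-type replicate 4), and that of the p53 targets from -0.003 (without deleted replicate 4) to 0.043 (without wild-type replicate 3). By fry, which tests a list against no change and not against other genes, both lists passed in the upward direction (adjusted p = 0.00218 for p53 targets and 0.003 for apoptosis). The mitochondrial nuclease gene Endog rose 3.18-fold and Bok fell by 0.63 on the log2 scale. Integrated stress response genes were higher in 8 of 26 and lower in 8, with a median of -0.09, a mean of 0.04 and a test that pointed up (camera adjusted p = 0.973). Slc7a5, an amino acid transporter gene, rose from 105 ± 7.88 to 164 ± 18.6 CPM.

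Cholesterol synthesis genes were lower in 19 of 23 and higher in 0. Fdft1 fell from 124 ± 3.78 to 60.4 ± 4.67 CPM, Fdps from 31.7 ± 2.14 to 14.5 ± 0.782 CPM and Msmo1 from 89.0 ± 3.2 to 52.8 ± 3.72 CPM. The list had a median of -0.41 (camera adjusted p = 6.29e-07, and adjusted p = 0.278 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 49 of 79, higher in 11 and not past the test in 19. Rpl4 fell from 858 ± 31.1 to 426 ± 15.7 CPM and Rps4x from 194 ± 8.26 to 94.6 ± 1.87 CPM. The ribosomal list had a median of -0.39 (camera adjusted p = 7.89e-06, and adjusted p = 0.413 with an estimated correlation), and its levels are uncertain because ribosomal protein genes have many processed pseudogenes. Heat shock and chaperone genes were lower in 12 of 23 and higher in 4. Xbp1 fell from 95.1 ± 11.5 to 46.8 ± 2.06 CPM and Pdia6 from 310.0 ± 9.08 to 204 ± 4.51 CPM (list median -0.22, camera adjusted p = 0.0127, and adjusted p = 0.413 with an estimated correlation).

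Among the lists of energy metabolism, 1 of 3 was called. Nuclear-encoded respiratory chain genes were higher in 16 of 74 and lower in 25 (median -0.04, camera adjusted p = 0.30), with Ndufb2 lower by a log2 fold change of -0.81. Genes encoded by mitochondrial DNA were higher in 6 of 14 and lower in 0, with CYTB at 3330 ± 232 against 2330 ± 171 CPM. That list had a median of 0.39 (camera adjusted p = 0.0442, and adjusted p = 0.731 with an estimated correlation). It lost its call without wild-type replicate 1 (median 0.33) or 4 (0.32) and without deleted replicate 1 (0.36) or 4 (0.34). Glycolysis genes were higher in 3 of 19 and lower in 7 (median -0.19, camera adjusted p = 0.138), Hk1 and Eno2 among the lower ones. Immediate early genes were higher in 12 of 18 and lower in 3 (median 0.38, camera adjusted p = 0.020, and adjusted p = 0.42 with an estimated correlation). Egr1 rose 3.78-fold and Arc 2.07-fold, while Fosl2 fell by 1.59 on the log2 scale.

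Markers of non-neural cells were higher in Taf8-deleted cortex. Endothelial and pericyte markers were higher in 16 of 20 and lower in 0, with Vtn at 20.6 ± 3.96 against 9.83 ± 0.589 CPM and the tight junction gene Cldn5 at 35.4 ± 4.51 against 24.7 ± 0.343 CPM (median 0.33, camera adjusted p = 0.000929, and adjusted p = 0.586 with an estimated correlation). Meningeal fibroblast markers were higher in 11 of 17, with Col1a2 at 19.8 ± 12.4 against 3.94 ± 1.62 CPM (median 1.23, camera adjusted p = 0.0291, and adjusted p = 0.731 with an estimated correlation). Their mean log2 CPM was 2.42, 2.99, 3.14 and 0.99 in the 4 deleted libraries and 1.13, 1.05, 0.85 and 1.72 in the wild-type libraries, so deleted replicate 4 lay among the wild-type values. Microglia and macrophage markers were higher in 10 of 20 and lower in 1, with C1qb 1.64-fold higher (median 0.39, camera adjusted p = 0.0382, and adjusted p = 0.586 with an estimated correlation). Red blood cell markers were higher in 7 of 11 (median 0.57, camera adjusted p = 0.0382, and adjusted p = 0.586 with an estimated correlation). Interferon response genes were higher in 13 of 19 and lower in 2, with Mx2 4.15-fold and Oasl2 2.57-fold higher, and Ifit2 lower by a log2 fold change of -1.09 (median 1.00, camera adjusted p = 0.020, and adjusted p = 0.685 with an estimated correlation). Without wild-type replicate 3 the microglia, meningeal, red blood cell and interferon lists lost their call, at medians of 0.42, 1.13, 0.44 and 0.90. The microglia list also lost it without wild-type replicate 1 (0.34) or deleted replicate 3 (0.29), and the red blood cell list without deleted replicate 2 (0.51). Upper-quartile scaling and library size alone ended the microglia, meningeal and red blood cell calls. With the meningeal level as a covariate, added after seeing the data, the microglia (0.17), red blood cell (0.20) and interferon (0.60) lists were not called, and the endothelial list was called at a median of 0.15.

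Choroid plexus and cortical hem markers varied from library to library within each group. Their median was 1.16, yet 2 of 15 were higher and 0 lower (camera adjusted p = 0.645). Without deleted replicate 1 the median was -0.04, and without deleted replicate 4 the list passed at a median of 1.198 (camera adjusted p = 0.0172). It also passed with Xist as a covariate (median 2.71, camera adjusted p = 0.00742). Of the higher genes, Msx1 lost its call with limma voom (log2 fold change 1.52), without wild-type replicate 2 (1.58), without deleted replicate 1 (1.45) or 2 (1.603), and with the meningeal covariate (0.29). Without wild-type replicate 4 it was at 2.36. Kl lost its call with the meningeal (1.08) and Xist (1.41) covariates. Markers of olfactory, thalamic and other regions outside the cortex gave 1 lower and 0 higher of 6 tested, Olig3 being the lower one (median 0.13, mean -0.07, camera adjusted p = 0.755). Olig3 lost its call with limma voom (adjusted p = 0.0606) and with the meningeal covariate (adjusted p = 0.1), and its log2 fold change ran from -1.867 without wild-type replicate 1 to -0.844 without wild-type replicate 2. Without wild-type replicate 2 the median of that list was 0.31, and without deleted replicate 2 it was -0.08. Adjusted over the list alone, higher and lower counts were 9 and 12 for apoptosis, 2 and 16 for deep-layer markers, 9 and 9 for the integrated stress response, 4 and 13 for heat shock and chaperones, and 5 and 0 for mitochondrial DNA. They were 0 and 20 for cholesterol synthesis, 8 and 0 for red blood cells, 0 and 0 for choroid plexus, 0 and 9 for oligodendrocyte precursors and astrocytes, 0 and 0 for regions outside the cortex, and 38 and 1 for histones. In the other 20 lists, counts adjusted over the list alone equalled those given above. Of the 31 lists, 18 were called by camera, 21 by fry, and 0 by camera with an estimated correlation, where 5 had an unadjusted p under 0.05. In the 18 splits that put 2 libraries of each genotype on both sides, camera called 4 to 13 lists, with a median of 8.5.

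**Figure D4:**
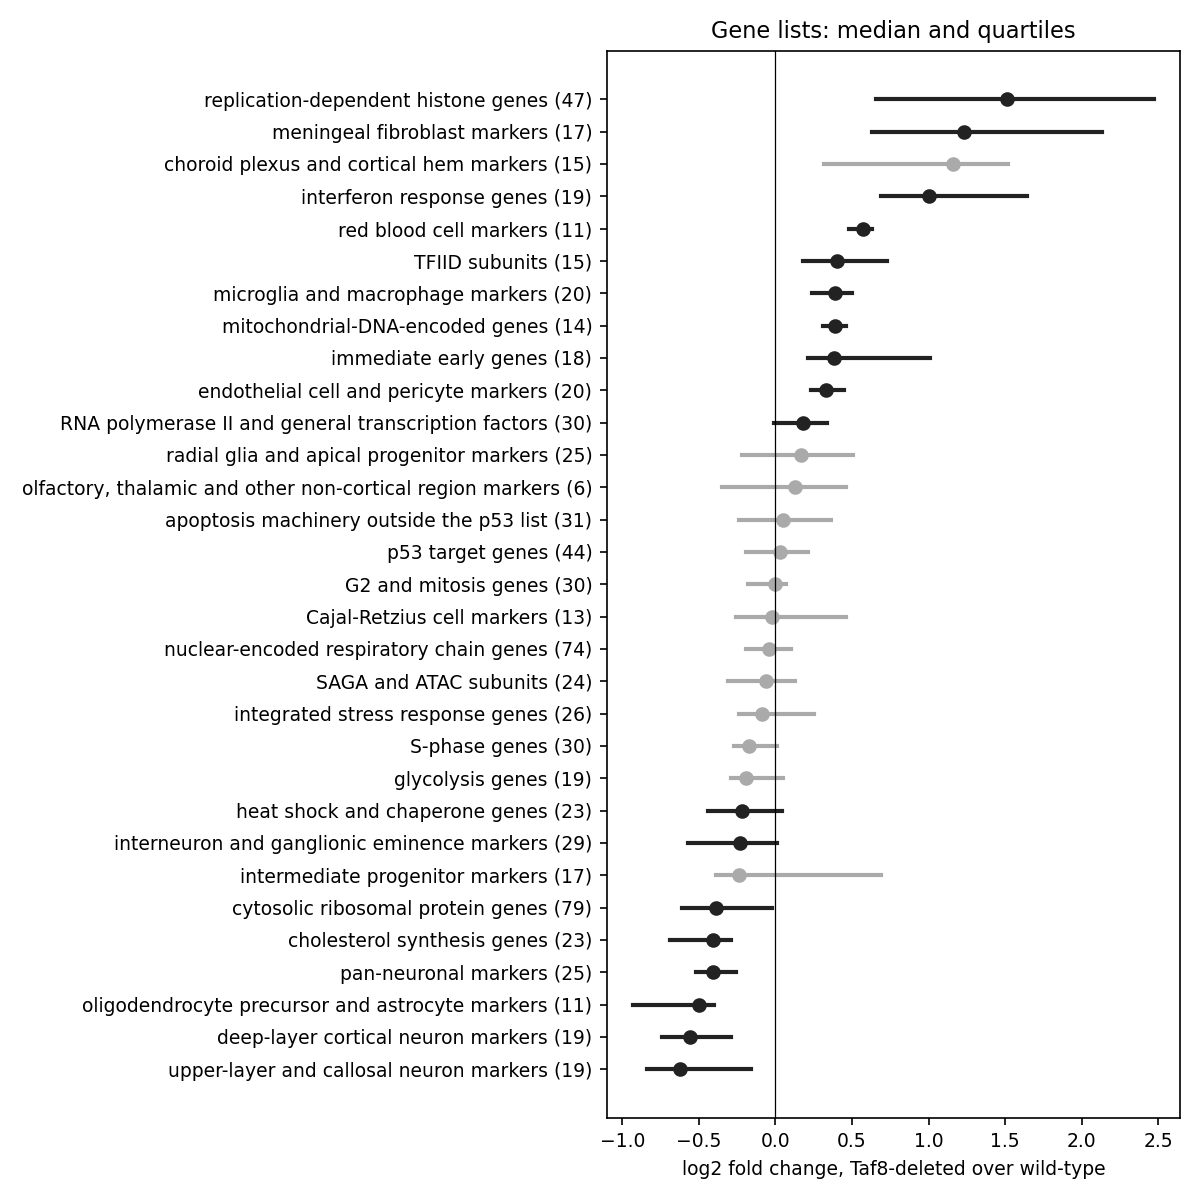
Median (point) and quartiles (line) of the log2 fold change, Taf8-deleted over wild-type, of the tested members of each of 31 gene lists, with the number of tested members in parentheses. Black marks the 18 lists with camera adjusted p under 0.05 and grey the rest, and the medians run from -0.62 for upper-layer markers to 1.51 for histone genes.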

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

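The tests of S-phase genes, of other RNA without a poly(A) tail, of oligodendrocyte precursor and astrocyte markers and of the meningeal covariate on neuron and vascular markers were chosen only after their results, or closely related ones, had been seen. A library far from the other 3 of its group was looked for in 362 groups of values, and 29 were found, where chance flags about 1 in 20 groups. Among the genes with the largest changes, the distant values in deleted cortex were Ccl27a at 20.2 CPM in replicate 3, Ndufs5 at 13.3 and H2ac6 at 16.1 CPM in replicate 1, Htr3a at 0.941 CPM in replicate 2 and Mc4r at 2.24 CPM in replicate 3. In wild-type cortex they were H2bc6 at 0.867 CPM and Sstr3 at 11.1 CPM in replicate 4, and Bcl6 at 11.1 CPM in replicate 1. Among list members, wild-type replicate 3 stood apart for Taf6 (75.1 CPM), Hes6 (125 CPM), Sox5 (338 CPM), Ube2c (91.1 CPM) and Rps4x (182 CPM). Other wild-type values were Atxn7l3 at 277 CPM in replicate 1, Sdf2l1 at 25.9 and Tcf7l2 at 38.6 CPM in replicate 2, and Kat2b at 29.7 CPM in replicate 4. Deleted replicate 4 stood apart for Diablo (77.2 CPM), Syn1 (63.1 CPM), Cacna2d2 (84.1 CPM), Arc (15.7 CPM), Ier2 (48.3 CPM), Fn1 (208 CPM) and Hba-a1 (53 CPM). Deleted replicate 1 did for Bok (23.5 CPM), Otx2 (22.0 CPM) and Olig3 (0.791 CPM), and deleted replicate 2 for Crabp2 (19.8 CPM) and the deep-layer list (mean log2 CPM 5.33).

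The rise of histone genes was set against 3 technical or compositional explanations. More cells in S phase would raise the S-phase list, but its median log2 fold change was -0.165 (95% bootstrap interval -0.251 to -0.015), so no rise was seen. A fall of that list was not called by camera (adjusted p = 0.0708) or by fry (adjusted p = 0.131). Bootstrap intervals here and below resample genes and not embryos, so they leave out the spread between embryos. Reads moving between near-identical copies is argued against by the sum over 63 genes, whose log2 ratio was 2.215 with every deleted library above every wild-type library. A greater carry-over of RNA without a poly(A) tail stays open. The 7 other such RNAs over 200 bases had a median of 0.442 (0.319 to 0.701). That is below the histone list median of 1.51 but above 0, so part of the rise may come from carry-over. The 7 were all small RNA types such as snoRNA, and ribosomal RNA was not among them, so they cannot decide the question. The most abundant row of the table, whose RNA type is not given here, was also higher in every deleted library. It was not among the 7. An effect of Taf8 loss on histone transcripts stays open as a hypothesis, with litter or batch untested.

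Genes of long non-coding RNA were higher as a class: 406 of 691 rose and 73 fell, with a median log2 fold change of 0.622 against -0.005 for 14135 protein-coding genes. Low expression is argued against, since 0 of 10000 sets of coding genes matched on expression had a median as high. Reads from introns of coding genes are argued against by 328 such genes overlapping no coding gene, with a median of 0.548 (0.443 to 0.672). Reads from neighbouring coding genes stay open and may account for part of the rise. The 144 genes more than 5 kb from any coding gene had a median of 0.279 (0.17 to 0.444). A greater carry-over of RNA without a poly(A) tail also stays open and was not tested for this class. The 7 small RNAs without a tail had a median of 0.442 (0.319 to 0.701).

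Neuron markers fell while vascular and meningeal markers rose. A lower share of neurons alone would raise the markers of every other cell type. Oligodendrocyte precursor and astrocyte markers (11 genes) instead had a median of -0.504 (-1.316 to -0.394), against 0.332 (0.25 to 0.434) for vascular markers. Radial glia markers went both ways, with 13 of 25 higher and 8 lower (median 0.17, camera adjusted p = 0.30). A lower share of neurons therefore stays open as part of the fall. Meningeal tissue carried along in the dissection is argued against as the whole cause of the fall in neuron markers, since the 63 neuron markers had a median of -0.343 (-0.482 to -0.246) with the meningeal level as a covariate and -0.439 without it. Of these, the deep-layer list went from -0.557 to -0.343. For the vascular rise it stays open, since the vascular median was 0.146 (0.09 to 0.23) with that covariate, an interval that spans 0.5 of the value without it. Gene length is argued against, since 0 of 10000 length-matched sets had a median as low. A change in maturation or cell makeup after Taf8 loss, and a difference of age or litter between the groups, stay open and were not tested.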

How the results depend on the processing

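Taf8 kept its direction and its call in every alternative, with log2 fold changes of -5.89 to -5.67. Across the alternatives 0 genes were called in the opposite direction, and of the values for named genes 67 lost and 17 gained a call and 7 changed sign. Of the 67, 47 came with Xist as a covariate. With that covariate 900 genes were higher and 1107 lower, and Xist itself differed between the groups (0.05 to 0.17 against 0.37 to 0.81 CPM), so the fit has little left to tell group from covariate. In that fit log2 fold changes were -0.022 for Taf1, 0.005 for Taf3 and -0.067 for Tbx21, and list medians were -0.037 for radial glia, 0.361 for immediate early genes, 0.087 for mitochondrial DNA, 2.713 for choroid plexus, which passed, and -0.737 for regions outside the cortex. Against a 1.2-fold change 2307 genes were higher and 2328 lower, since small changes no longer count. With Xist as a covariate 9 TFIID subunits lost their calls, and 7 lists that stayed called moved by over 1.5 times to -0.413 (interneurons), 1.64 (interferon response), 0.773 (microglia), 0.516 (endothelium), 3.442 (meninges), 0.947 (red blood cells) and -0.326 (oligodendrocyte precursors and astrocytes). The other such moves were to 0.782 (meninges, quality weights), 0.805 (meninges, choroid plexus covariate), and -0.343 (deep-layer) and 0.146 (endothelium) with the meningeal covariate. With the replicate block 4115 genes were higher and 4170 lower, and the S-phase list passed (median -0.16) and Msx1 did not (1.755). Libraries with the same number did not deviate together (r = -0.285, 0.014, -0.067 and -0.464), so no pairing by number was seen. These are deviations from means of 4 libraries, so they cannot exclude a pairing.

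With an estimated correlation 0 of the 18 called lists passed. Their medians do not depend on that choice: 0.397 for TFIID, 0.178 for RNA polymerase II and general factors, -0.412 for pan-neuronal, -0.557 for deep-layer and -0.617 for upper-layer markers, -0.233 for interneurons, 0.38 for immediate early genes, -0.215 for chaperones, -0.385 for ribosomal proteins, 0.389 for mitochondrial DNA, -0.408 for cholesterol synthesis, 0.997 for interferon response, 0.392 for microglia, 0.332 for endothelium, 1.23 for meninges, 0.571 for red blood cells, -0.504 for oligodendrocyte precursors and astrocytes, and 1.512 for histones. With fry the SAGA and ATAC (-0.063), p53 (0.032), apoptosis (0.046), Cajal-Retzius (-0.015) and glycolysis (-0.185) lists passed. Despite its negative median, the Cajal-Retzius list was called as higher (fry adjusted p = 0.0125). The mitochondrial DNA (0.389) and meningeal (1.23) lists did not pass with fry. For the other changes below the cause was not tested. Taf1 gained a call with upper-quartile scaling, library size alone, quality weights and without wild-type replicate 3. With upper-quartile scaling Taf3 was at 0.011, and mitochondrial DNA (0.418), microglia (0.422), meninges (1.258) and red blood cells (0.601) lost their call. With library size alone Taf3 was at 0.024, and the same 4 lists lost it at 0.431, 0.435, 1.27 and 0.614. Without a filter the S-phase list passed (-0.169) and the test of the integrated stress response turned down (-0.088). With the stricter filter mitochondrial DNA (0.405), interferon response (0.827) and red blood cells (0.555) lost their call. With quality weights S-phase (-0.205) and glycolysis (-0.241) passed, and the integrated stress response test turned down (-0.097).

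In fits added after seeing the data, the meningeal covariate put Rspo2 at -0.735, S-phase at -0.213 (passed), the integrated stress response at -0.069 and choroid plexus at -0.735, and ended the calls of interferon response (0.595), microglia (0.168), meninges (-0.092) and red blood cells (0.195). The choroid plexus covariate put its own list at -0.176. A covariate made from a list removes that list's own difference by construction. Without wild-type replicate 4 and deleted replicate 1 mitochondrial DNA lost its call (0.311). Leaving out 1 library at a time, ranges were -0.672 to 0.157 for Tcf7l2 (positive without wild-type replicate 2), -0.239 to -0.141 for S-phase (passed without wild-type replicate 3 or deleted replicate 2), -0.116 to -0.056 for the integrated stress response, 0.315 to 0.502 for mitochondrial DNA (lost without wild-type replicate 1 or 4 or deleted replicate 1 or 4) and -0.279 to -0.158 for glycolysis (passed without wild-type replicate 3). They were 0.895 to 1.252 for interferon response (lost without wild-type replicate 3), 0.286 to 0.462 for microglia (lost without wild-type replicate 1 or 3 or deleted replicate 3), 1.041 to 1.604 for meninges (lost without wild-type replicate 3), 0.442 to 0.696 for red blood cells (lost without wild-type replicate 3 or deleted replicate 2), -0.045 to 1.31 for choroid plexus (passed without deleted replicate 4) and -0.078 to 0.314 for regions outside the cortex. The medians of 4 lists near 0 also took either sign: -0.003 to 0.043 for p53 targets, -0.034 to 0.094 for apoptosis, -0.092 to 0.088 for Cajal-Retzius and -0.084 to 0.041 for G2 and mitosis. DESeq2 gave no list test. Genes near the floor of 3 counts are the ones that depth limits.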

Other observations

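The most abundant row of the table, Entrez gene ID100861531, has no symbol in the tables used here and was chosen after its values were seen. It was at 11700 ± 2520 CPM in Taf8-deleted and 4420 ± 746 CPM in wild-type cortex, a log2 fold change of 1.40 (SE 0.16, adjusted p = 3.42e-05 by edgeR), and was higher in all 4 deleted libraries than in all 4 wild-type libraries. The top gene of each library held 0.41% to 0.54% of counts in wild-type and 0.80% to 1.38% in Taf8-deleted cortex. The RNA type of ID100861531 is not given in the tables used here, so it was not part of the test of other RNA without a poly(A) tail. Whether its rise comes from the cells or from how the libraries were made was not tested.

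All 35 splits of the 8 libraries into 4 and 4 were fitted. The real split gave 4624 and 4633 genes in its 2 directions, and the highest count in a direction among the other splits was 1. Thus 1 of the 35 splits, the real one, gave a result as large, which is the smallest share possible. Every other split mixes the genotypes, so the group difference adds to the spread within its sides and few calls can be made. The splits also cannot tell genotype from litter or batch. For the lists called by camera the real split was not the highest. It gave 18 lists, another split gave 20, and 2 of the 35 splits gave as many as the real one. That other split exchanges wild-type replicate 3 and deleted replicate 4, and the other 15 splits that exchange 1 library of each genotype gave 9 to 17 lists. Why it gave more was not tested. The 18 splits with 2 libraries of each genotype on both sides gave 4 to 13 lists, with a median of 8.5, so camera with its preset correlation also calls lists where genotype is balanced.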
